A study of Danio rerio with 4 samples.

How the data were processed

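Whole zebrafish embryos at 24 and 96 hpf, with 0 or 3.9 µM copper, were profiled on 4 one-colour Agilent arrays, with 1 array per group. Per the labels' protocols, RNA was extracted with TRIzol, and per the series' design text it was labelled with the Quick Amp protocol (version 5.7), scanned, and read with Agilent Feature Extraction 11.0.1.1. The deposited scanner files hold spot intensity values that, per the file headers, Feature Extraction subtracted for background and did not normalize between arrays, together with flags. Per the same design text, the authors applied quantile normalization in GeneSpring GX 11.5.1, kept genes detected in at least 2 of 4 samples and selected by fold change. The authors' deposited table of listed probes holds log2 fold changes, absolute fold (a ratio), quantile-normalized log2 values and raw intensity values, with probe coordinates on Zv9. Probe coordinates are printed only from that table. Per the file headers all 4 arrays came from one slide and scan, so no scan batch separates the groups. No spot was saturated.

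Here log2 of the processed intensity was averaged over spots of a probe and quantile-normalized over the 4 arrays. Control spots and spots with outlier flags were left out, which removed 34 of 43603 probes. Probes well above background on at least 2 of 4 arrays (36026) were compared. Of the 43569 probes kept, 25957 were named for 13366 genes through RefSeq accessions and a table of assembly GRCz12tu used for names only, and 17612 stayed unnamed. A gene's value is that of its detected probe with the highest mean signal. Quantile normalization forces equal distributions on the arrays, so a shift of most genes would be removed. The processed intensity holds surrogate values at its low end, so small folds of dim probes are compressed or unreliable.

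Groups follow the sample labels, although file names give the opposite treatment. With 1 array per group, differences at an age carry no test, and probes past 2-fold are counted. A probe well above background on only one array of an age has a bound, computed as the bright value against the higher of the dim value and the lowest normalized value among probes well above background on the dim array, and for age likewise where a probe was dim on both arrays of an age. Counts of genes at bounds, and of list members well above background on either array, leave out probes dim on both arrays of the age; these were chosen after the values were seen. Gene lists (39, fixed before the data were examined) are given by the percentile of their median among 10000 random lists of the same size matched in 20 bins of mean signal. Age and copper were fitted over the 4 arrays with limma 3.58.1 (R 4.3.3), lmFit and eBayes with trend, and Benjamini-Hochberg adjustment, tested on simulated data. Nothing says whether an array held a separate pool of embryos per treatment, so the p-values measure only the spread between these arrays. Per probe, the 1 residual degree of freedom of this fit is the difference of the copper change between the ages. It is not a spread between replicates, and the test of copper asks for a like change at both ages. Other steps used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

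Genes are named by a rule fixed in advance. It takes, per age, the 12 highest and 12 lowest genes measured on both arrays with the same sign under 3 normalizations and on their other probes, the 5 largest bounds in each direction, up to 4 members of each list, and, for age, 8 genes in each direction past the threshold. The genes mt2, hmox1a, hsp70l and atp7a are added in any case. One gene that the rule takes at 24 hpf is not reported here. For age, calls among list members are counted with adjustment over all probes and over the list alone.

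Alternatives were scaling by the 75th percentile, normexp background correction (offset 50) before quantile normalization, detection on all 4 arrays, no filter, a 4-fold threshold, the treatment as file names give it, counts of genes, eBayes without trend, mean of detected probes, mean of the list, and list members measured on both arrays of an age. The planned normexp step named the mean spot intensity, which was not used here; the median spot and background intensity of the deposited scanner files took its place. Upstream and downstream probes of a gene were ordered by the Zv9 coordinates of the authors' deposited table, for pairs at least 200 bases apart. Most spike-in controls were near background and they were not used here.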

Results

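Gene expression was measured in whole zebrafish embryos at 24 and 96 hours post fertilization (hpf), raised without added copper or in 3.9 µM copper. The 4 arrays formed 4 groups of 1 array each, so a difference at one age is a difference between a pair of arrays, with no replicate check and no p-value. Between 33531 and 36468 probes were well above background on an array, or 76.9% to 83.6% of those read on it. The median signal was 364.6 on the 24 hpf array labelled copper and 161.7 on the 24 hpf array labelled control, and 189.7 and 193.6 on the corresponding 96 hpf arrays. Spots of one probe on one array differed by a median SD of 0.05 to 0.08 on the log2 scale, which covers printing and scanning error only. The number of arrays limits the precision of every comparison.

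The treatment in the sample labels was opposite to that in the names of the deposited scanner files and in the authors' deposited table, at both ages. Groups follow the sample labels, and each value below is the array labelled copper minus the array labelled control. If the file names are right, every sign at a single age turns. Metallothionein (mt2), a metal-binding protein whose gene is induced by metals including copper, was used as a check on the labels. At 96 hpf mt2 differed by 0.55 (log2) on its brightest probe, was higher in the array labelled copper on 3 of 3 probes, and differed by 0.63 under 75th-percentile scaling and 0.50 under normexp background correction. At 24 hpf mt2 was higher on 3 of 3 probes, by 0.029 on its brightest and up to 0.98 on another, but the brightest probe had no settled sign, with -0.22 under 75th-percentile scaling and -0.027 under normexp. The zinc exporter slc30a1a was 1.18-fold higher at 24 hpf and 1.32-fold higher at 96 hpf. Its difference at 24 hpf (0.24 in log2) was 0.13 under 75th-percentile scaling and 0.035 under normexp. The copper importer slc31a1 was 1.65-fold higher at 96 hpf on all 6 probes, and 1.32-fold lower at 24 hpf on its brightest probe, where 5 of 6 probes were lower. None of the 5 measured genes of the metallothionein and metal-responsive list reached 2-fold at either age. Of 11 copper handling genes 0 reached 2-fold at 24 hpf, and at 96 hpf the copper-transporting ATPase atp7a was not well above background in the array labelled copper and was at least 1.11-fold lower there. The heme oxygenase hmox1a was 1.33-fold higher at 24 hpf and 1.77-fold lower at 96 hpf, and the heat shock gene hsp70l differed by 0.054 (-0.027 under normexp) and -0.25.

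**Figure D1:**
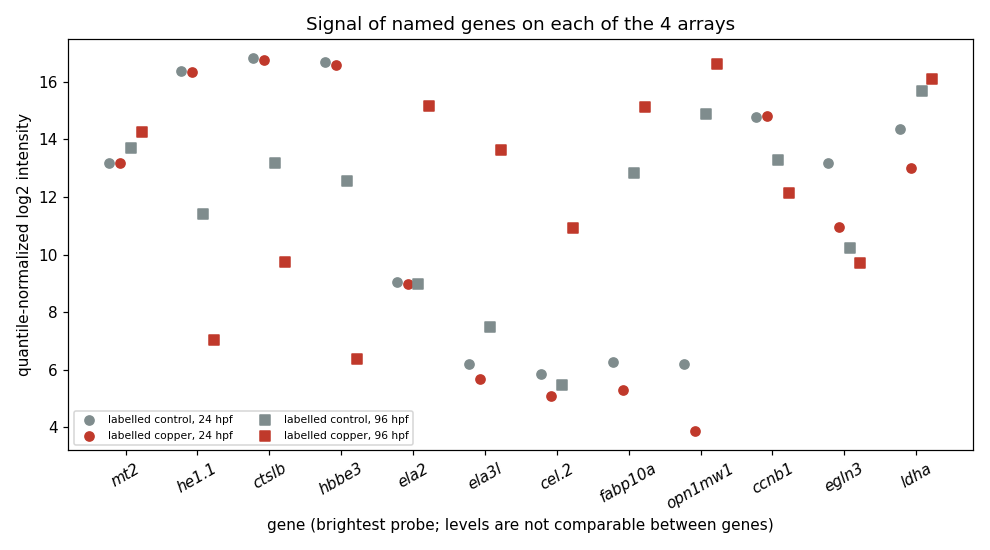
Quantile-normalized log2 intensity (y axis) of 12 named genes (x axis) on each of the 4 arrays, 1 point per array, circles for 24 hpf and squares for 96 hpf, grey for the arrays labelled control and red for those labelled copper. At 96 hpf ela2 was 71.9-fold higher and he1.1 20.8-fold lower in the array labelled copper.

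The comparison at 24 hpf asks how embryos in copper differed after their first day. In the array labelled copper, genes of the hypoxia and glycolysis list were lower, among them the oxygen sensor egln3 (4.64-fold, 2 of 2 probes), the collagen prolyl hydroxylase subunit p4ha2 (2.65-fold, 3 of 3 probes) and lactate dehydrogenase ldha (2.58-fold, but -0.04 in log2 on its other probe). The oxidoreductase ero1a, which forms disulfide bonds in the endoplasmic reticulum, was 4.84-fold lower. Inflammatory response genes were also lower by their brightest probes, among them tnfb (2.85-fold), socs3a (2.37-fold) and ptgs2b (2.18-fold). Cartilage collagen col2a1a was 6.14-fold higher on 4 of 4 probes. The chaperone genes bag3 and dnajb1b were 2.45-fold and 2.44-fold higher, on 1 probe each. Probes of one gene often differed at this age, by 2-fold or more in 27.7% of genes with several well-measured probes, and egln3, p4ha2, tnfb and col2a1a are genes whose probes all lay on one side. Because file names and labels conflict, which of these arrays came from embryos in copper is not settled.

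The largest differences at 24 hpf by the fixed rule were, on the higher side, pik3r2 (10.8-fold), gigyf2 (8.80-fold), slc34a2b (8.54-fold), the monoacylglycerol lipase mgll (8.31-fold), the serine hydroxymethyltransferase shmt2 (6.77-fold), znf609b (6.26-fold), col2a1a, ppp2r5eb (5.96-fold) and the fibrillin fbn2b (5.63-fold). Sipa1l1, mfsd14a1 and the caspase casp6a were higher by 5.22-fold to 5.35-fold. On the lower side stood pdha1b (12.7-fold), sertad4 (6.14-fold), the T-box gene tbx4 (5.27-fold), the green-cone opsin opn1mw1 (5.01-fold), ero1a, zp3d.2 (4.81-fold), egln3, c6ast3 (4.50-fold), the carotenoid oxygenase bco2b (4.17-fold), the choline kinase chka (4.01-fold) and atg10 (3.85-fold). The values of pik3r2, sipa1l1, mfsd14a1, casp6a, fbn2b, pdha1b, sertad4, ero1a, zp3d.2, c6ast3 and bco2b rest on 1 probe each. The other probe of a gene went the same way but by less than 2-fold for gigyf2 (0.048 in log2), slc34a2b (0.69), opn1mw1 (-0.77), chka (-0.84) and atg10 (-0.058), so these folds are not shared by all probes. Among genes not well above background in one of the arrays, erlin1 was at least 7.36-fold higher and rpz3 at least 3.06-fold lower. In the authors' deposited table, whose coordinates are on Zv9, the probe of pdha1b lies on chromosome 24 from 24881427 to 24881486 and that of egln3 on chromosome 17 from 9776824 to 9776883.

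For each of the 39 gene lists, 10000 random lists of the same size were matched on mean signal over the 4 arrays. At 24 hpf 5 lists lay below and 5 above the middle 95% of their random lists. The other 29 lay inside. The median gene differed by -0.26 at this age, and the median probe by -0.12, or 0.032 under 75th-percentile scaling, so a list is read against its random lists. However, random lists were not matched on signal at 24 hpf alone. The tenth of genes that rose most from 24 to 96 hpf had a median of -0.52 at 24 hpf. The photoreceptor and hormone lists, which rose with age, were thus not set against genes of like signal at 24 hpf. By brightest probes, the inflammatory list had a median of -0.73, with 0 of 19 measured genes above 0 and 5 lower by 2-fold or more. Not all probes of its genes were lower. Another probe was higher for irg1l (by 0.45, 1 of 2 probes) and c3a.2 (by 1.05, 1 of 3 probes), while il1b (2 of 2) and cebpd (3 of 3) were lower on every probe. The photoreceptor list had a median of -0.70 over 26 genes, and 4 of the 23 well above background on either array were lower by 2-fold, among them opn1mw1 (2 of 2 probes lower) and opn1mw2, whose other probe was higher by 0.80. The hypoxia and glycolysis list had a median of -0.60 and 6 of 22 genes lower by 2-fold, while the glucose transporter slc2a1a was 2.48-fold higher. The hormone list (-0.62) and the Wnt list (-0.44) also lay below, the latter with 4 of 38 genes higher and 1 lower by 2-fold. The lists above were the unfolded protein response (median 0.12, calr3b 4.15-fold and atf6 3.21-fold higher), lens (0.10), heat shock (0.034, 5 of 18 genes higher by 2-fold), skeletal muscle (0.028) and cell cycle (-0.024). The size of these medians depended on the processing, and with the mean of detected probes they were 0.79 for heat shock, 0.65 for the unfolded protein response and 0.23 for muscle. The sign also turned, to -0.041 for the unfolded protein response and -0.26 for muscle under 75th-percentile scaling, to -0.023 for heat shock under normexp, and to 0.40 for cell cycle with the mean of detected probes. Of 7 alternatives, the place outside the random lists held in 2 for Wnt, 3 for hormones, 5 for photoreceptors and 6 for heat shock.

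Over all probes, 3406 were higher and 2198 lower by 2-fold or more at 24 hpf, or 60.8% higher, and this share was 84.5% under 75th-percentile scaling and 78.2% under normexp. By the brightest probe of each gene the balance turned, with 442 genes higher and 756 lower, or 374 and 710 with probes dim on one array at their bounds and those dim on both left out. Among 6289 genes with at least 2 probes well above background on all 4 arrays, the probes' differences lay 2-fold or more apart in 1745 genes (27.7%) at 24 hpf and in 153 (2.43%) at 96 hpf. The dimmest probe of a gene exceeded its brightest by a median of 0.51 at 24 hpf and by -0.09 at 96 hpf. Among 7096 genes with 2 or more detected probes, 87 were higher and 57 lower by 2-fold or more on every detected probe. This count was chosen after the data were seen and left out genes with 1 detected probe.

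The comparison at 96 hpf asks the same of older embryos. Digestive enzymes of the exocrine pancreas were far higher in the array labelled copper, with 14 of 16 measured genes of the list higher by 2-fold or more and a list median of 4.54. The elastases ela2 and ela3l were 71.9-fold and 70.4-fold higher, syncollin sycn.2 was 62.6-fold higher, and the lipase cel.2 and the amylase amy2a were 43.9-fold and 38.0-fold higher. Of 6 hatching gland genes 3 were lower by 2-fold or more, he1.1 by 20.8-fold, he1.2 by 18.9-fold and the cathepsin ctslb by 10.9-fold; he1.1 and he1.2 encode hatching enzymes that dissolve the egg envelope. The related he1.3 was 1.13-fold higher, with 1 of 3 probes lower, and the gland's transcription factor klf17 was 1.46-fold higher on 3 of 3 probes. The remaining gene of the list, agr1, was 1.82-fold lower on 2 of 2 probes. The embryonic globin hbbe3 was 72.0-fold lower. The array labelled control is the one with low pancreas and high he1.1, he1.2 and ctslb signal, and the file names call that array copper.

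The largest differences by the fixed rule at 96 hpf were led by digestive enzymes on the higher side. They were ctrb.2 (202.9-fold), c6ast4 (192.7-fold), ela2, ela3l, sycn.2, ctrb.3 (43.7-fold), cel.2, cela1.1 (41.7-fold), the chitinase chia.2 (39.3-fold), ctrl (38.7-fold), amy2a and the trypsin prss59.1 (35.9-fold). The intestinal brush-border protease mep1a.2 was not well above background in the array labelled control and was at least 60.2-fold higher in the array labelled copper, and amy2al2 and krt93 were at least 30.8-fold and 30.3-fold higher. On the lower side were hbbe3, gpib (36.4-fold), he1.1, he1.2, ctslb, the fatty acid binding protein fabp4b (5.49-fold), the globin hbaa2 (5.40-fold), dao.1 (5.07-fold), the heme synthesis enzyme alas2 (4.21-fold, 4 of 4 probes), the parathyroid hormone pth1a (4.13-fold), rfesd (3.82-fold) and rnf126 (3.74-fold). Values that rest on 1 probe each include ctrb.2, c6ast4, ctrb.3, cel.2, amy2a, mep1a.2, amy2al2 and krt93 on the higher side. On the lower side they include hbbe3, gpib, he1.1, fabp4b, hbaa2 and dao.1. In the authors' deposited table the probe of he1.1 lies on chromosome 22 from 14237933 to 14238075 and that of hbbe3 on chromosome 12 from 21691973 to 21692032 (Zv9).

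At 96 hpf 14 lists lay above and 8 below the middle 95% of random lists. After the exocrine pancreas came the intestine (median 1.85, 14 of 22 genes higher by 2-fold, alpi.2 17.0-fold) and photoreceptors (median 1.45, 19 of 26 genes higher by 2-fold, pde6ha 5.13-fold and opn1mw2 4.57-fold). Genes of ionocytes and kidney had a median of 0.55 with 7 of 28 higher by 2-fold, hormone genes 0.43 with all 16 well above background on either array above 0, and liver genes 0.31 with 5 of 26 higher by 2-fold, among them the transport proteins ttr (15.8-fold) and fabp10a (4.90-fold). The metallothionein list (0.35), the hypoxia and glycolysis list (0.12) and the keratin list (0.051) also lay above. Glial genes had a median of 0.30, with s100b 2.98-fold and the myelin protein mpz 2.64-fold higher. Below lay the hatching gland list (median -2.16, 3 of 6 genes lower by 2-fold), globins and erythroid genes (-0.65, 6 of the 20 well above background on either array), cell cycle genes (-0.64, 28 of 29 below 0) and pigment cell genes (-0.61, pmelb 2.73-fold lower). So did neural progenitor genes (-0.46, with dlb the 1 gene of 17 lower by 2-fold), lysyl oxidase and notochord genes (-0.41, 2 of 10 above 0), the unfolded protein response (-0.34, calr3b 2.13-fold lower) and the Wnt list (-0.19). The cyclin ccnb1 was 2.23-fold lower on 6 of 6 probes and the kinases aurka and cdk1 were each 2.09-fold lower. Of 7 alternatives, the place outside the random lists held in 2 for hypoxia and glycolysis, 4 for Wnt and 6 each for metallothionein, keratins and the unfolded protein response.

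**Figure D2:**
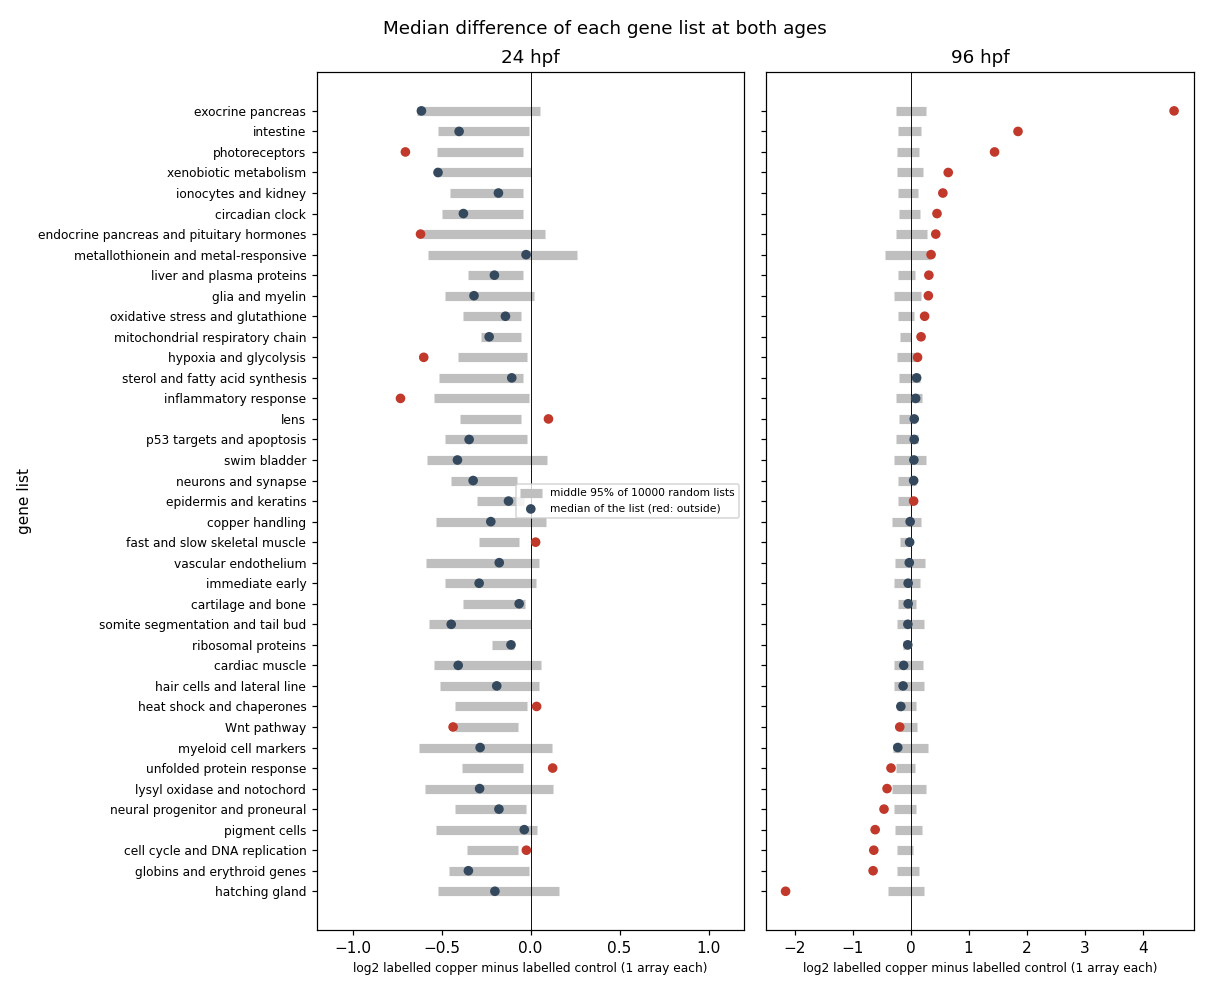
Median log2 difference of each gene list (x axis, array labelled copper minus array labelled control, 1 array each, with a wider scale at 96 hpf) at 24 hpf (left) and 96 hpf (right), for each list on the y axis. Grey bars span the middle 95% of 10000 random lists matched on mean signal and red points lie outside them, with the exocrine pancreas at 4.54 and the hatching gland at -2.16 at 96 hpf.

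At 96 hpf 1872 probes were higher and 1139 lower by 2-fold or more, or 62.2% higher, a share that was 54.7% under 75th-percentile scaling and 79.3% under normexp. By the brightest probe of each gene, 699 genes were higher and 266 lower, or 669 and 203 with dim probes treated as at 24 hpf. Of the 7096 genes with 2 or more detected probes, 219 were higher and 65 lower by 2-fold or more on all of them.

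No gene passed the test of copper over both ages. An additive limma model of age and copper over the 4 arrays, with 1 residual degree of freedom, called 0 of 36026 probes higher and 0 lower at an adjusted p under 0.05, and 710 probes had an unadjusted p under 0.05. The smallest Benjamini-Hochberg adjusted p was 0.9999. The same model was run on simulated data. It recovered 86% of probes changed by 3 on the log2 scale and 4% of those changed by 1. There were 10 false calls among the other simulated probes, and a shared change of 2-fold was mostly out of reach there. Of the unchanged simulated probes 5.4% had an unadjusted p under 0.05, a larger share than the 710 of 36026 here. The simulated spread thus differed from that of these arrays, and the recovery may not hold for them.

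Between 24 and 96 hpf, genes of the eye were among those that rose most. The same limma model, in which each age has 2 arrays of different treatment, called 5364 probes higher and 5670 lower at 96 hpf. Rhodopsin (rho) rose by 11.14 (log2, SE 0.53, adjusted p = 6.85e-07), the cone transducin subunit gnb3b by 11.20 and opn1mw1 by 10.71. The red-cone opsin opn1lw2 (adjusted p = 1.56e-07), the ultraviolet-cone opsin opn1sw1 and the chymotrypsinogen ctrb.1 were not well above background on either 24 hpf array. They were at least 5476-fold, 1800.5-fold and 1165-fold higher at 96 hpf. The p of opn1lw2 thus rests on dim 24 hpf values. The smallest adjusted p of the limma age test over all probes was 1.56e-07 here, 0.00019 by eBayes without trend and 0.0035 without a filter, so the size of these p-values depended on the settings. Of 26 photoreceptor genes 24 rose (median difference 6.64), as did 27 of 30 lens genes (5.20), 11 of 16 exocrine pancreas genes (4.93) and 22 of 32 neuronal genes (2.43). With genes dim at one age set at their bounds, the medians were 6.64, 5.03, 4.75 and 2.43. Adjusted over the list alone, these counts were 25, 27, 14 and 23. The globin hbbe3 fell by 7.17 (SE 1.00, adjusted p = 0.000571), and he1.1 fell by 7.12. The left-side signal lft1 and the segmentation gene mespaa were not well above background on either 96 hpf array, and were at least 52.0-fold and 16.2-fold lower there. All 29 cell cycle genes fell (median difference -2.06), as did 6 of 6 hatching gland genes (-3.99) and 15 of 21 somite and tail bud genes (-2.38). Adjusted over the list alone, these counts were 29, 6 and 16. These signs do not depend on which array of an age was in copper.

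Differences at the 2 ages ran in opposite directions more than together. Across 12332 genes, which are not independent replicates, Pearson's r between the ages was -0.19 (Spearman's rho -0.24). This r was -0.12 under 75th-percentile scaling and -0.25 with detection on all 4 arrays. By the brightest probe, 27 genes were higher at both ages (25.1 for independent lists) and 33 lower at both (16.3), while 135 were lower at 24 hpf and higher at 96 hpf (42.9) and 28 the reverse (9.53). With dim probes at their bounds, these counts over 11916 genes were 8 (17.9), 22 (11.6), 115 (33.2) and 20 (6.27). The overlap counts were not run under another normalization or with another choice of probe, on which the counts at 24 hpf depended. The difference at 96 hpf followed the change with age, with r = 0.53 across genes. The median difference ran from -0.45 in the tenth of genes that fell most with age to 0.54 in the tenth that rose most. At 24 hpf r was -0.16 and moved to -0.018 under 75th-percentile scaling. The differences at the ages share no array, whereas a difference and the change with age come from the same arrays and are independent only where those arrays are equally noisy.

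**Figure D3:**
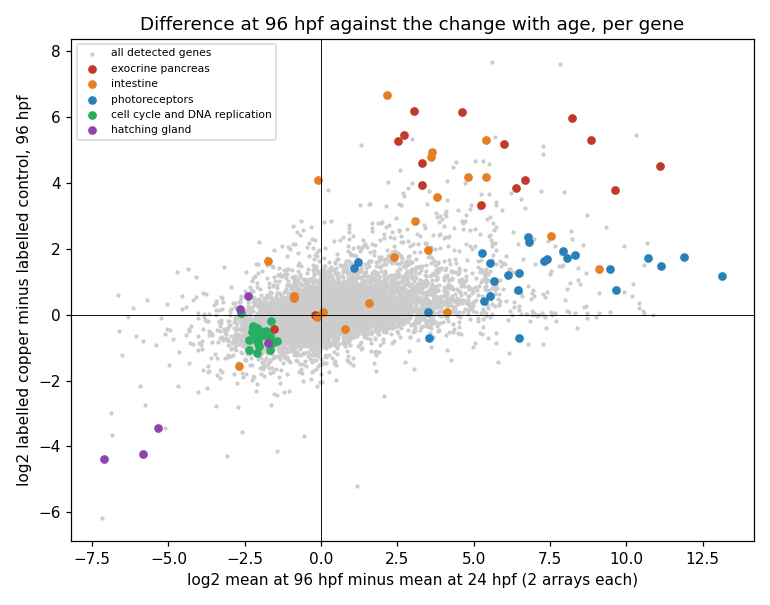
Difference at 96 hpf (y axis, log2, array labelled copper minus array labelled control) against the change from 24 to 96 hpf (x axis, log2, mean of the 2 arrays of each age), 1 point per detected gene, with 5 gene lists in colour. Genes that rose with age lay higher in the array labelled copper (r = 0.53 across genes).

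The authors' deposited table lists 5555 probes at 24 hpf and 2964 at 96 hpf that differ by 2-fold or more. Of these, 5548 and 2962 were also past 2-fold here. The sign in the authors' deposited table was opposite to the sign by the sample labels for all 5555 probes at 24 hpf and all 2964 at 96 hpf, with r = -0.999 at each age. By the authors' deposited table, 2170 probes at 24 hpf were higher and 3385 lower in the array it calls copper, and 1098 were higher and 1866 lower at 96 hpf.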

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

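Of the tests given here, the counts at bounds and those of the quantile step at 24 hpf, of the 96 hpf pattern and of the labels were chosen only after the result was seen. The direction of several differences was opposite at the 2 ages, and this contrast between ages was not tested, since each age has 1 array per group. In the array labelled copper, 135 genes were lower at 24 hpf and higher at 96 hpf by 2-fold or more. The reverse held for 28, and these counts were 115 and 20 with dim probes at their bounds. They are by the brightest probe of each gene and were not run under another normalization. There were 3 lists below random lists at 24 hpf and above them at 96 hpf: photoreceptors (-0.70, then 1.45), hormones (-0.62, then 0.43) and hypoxia and glycolysis (-0.60, then 0.12). Of 7 alternatives, only 3 kept hormones below at 24 hpf and only 2 kept hypoxia and glycolysis above at 96 hpf, so the contrast rests on the main processing for these lists; photoreceptors were kept in 5 and 7. There were 2 lists above and then below: the unfolded protein response (0.12, then -0.34) and cell cycle (-0.024, then -0.64).

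Labels and file names give opposite treatments. If the labels were exchanged at both ages, mt2 and the hatching gland genes would both be lower in the array labelled copper, the latter because copper is known to hinder hatching. At 96 hpf mt2 was 0.55 higher there, and the metallothionein and metal-responsive list had a median of 0.35 with 4 of 5 genes above 0, just outside the middle 95% of random lists, which ended at 0.34, and kept there in 6 of 7 alternatives, which argues against an exchange. With age 3 of the 5 genes of this list, mt2 among them, were higher at 96 hpf (list median 0.80, inside random lists). By limma 2 of the 5 rose and 1 fell at an adjusted p under 0.05, and mt2 did not pass (adjusted p = 0.0599). A difference in stage could therefore also raise some of them without copper. Of further genes looked at for the labels, slc31a1 was 0.73 higher at 96 hpf, and hmox1a (-0.83) and hsp70l (-0.25) were lower. Their signs held under 75th-percentile scaling and normexp, and no prediction was set for them. The hatching gland median was -2.16, which would argue for an exchange. However, this direction was first set the other way and turned after the value was seen. The median lies between 3 genes lower by 2-fold or more and 3 that were not. Of the latter, he1.3 (0.18) and klf17 (0.55) were higher and agr1 (-0.87, 2 of 2 probes) was lower. Which treatment is right cannot be told apart from these arrays, because mt2 and the other genes of its list differed by under 2-fold. At 24 hpf the brightest probe of mt2 had no settled sign, although 3 of 3 probes were higher. The list median by brightest probes was -0.026 at that age, inside random lists, with 2 of 5 genes above 0. The hatching gland genes at 96 hpf were divided, with 2 of 6 above 0, and also fall with age.

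Probes of one gene disagreed at 24 hpf, by 2-fold or more in 27.7% of genes with several well-measured probes. Without the quantile step (75th-percentile scaling) this share was 41.5%, which argues against that step as the cause. Under normexp background correction, with the quantile step kept, it was 19.9%. The share thus depended on the processing, and a part played by background handling was not tested. Among 181 genes with probes listed at 96 hpf, the upstream probe exceeded the downstream one by a median of 0.54 at 24 hpf (154 genes) and by -0.023 at 96 hpf, as uneven RNA quality or labelling along transcripts could give. Matching probes on brightness left a gap of 0.51, which argues against brightness alone, but the gap was 0.036 over the 18 genes whose upstream probe was the brighter one, so position stays open. A loss of upstream signal in the array labelled control, the form in which this explanation was first set out, is argued against by the gap to the 96 hpf arrays, which was 0.075 there and 0.63 in the array labelled copper. An effect of copper on the transcripts also stays open and was not tested.

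At 96 hpf digestive genes were higher and 3 of 6 hatching gland genes lower by 2-fold or more in the array labelled copper. A difference in the digestive organs alone is argued against by the photoreceptor median of 1.45, where the middle 95% of random lists ended at 0.15, and the normalization by an exocrine pancreas median of 4.65 under 75th-percentile scaling. A candidate explanation is a difference in developmental stage, with the array labelled control from less advanced embryos: across 12232 genes outside the digestive and hatching gland lists, the difference followed the change with age with r = 0.52. Lists that rose with age did not all follow, since lens (0.061), neurons (0.051) and cartilage and bone (-0.044) lay inside their random lists at 96 hpf, so a shift of all tissues alike is not shown. A slower development in copper could give this if the file names are right, and so could a chance difference in staging between the samples. An effect of copper under either labelling stays open and was not tested.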

How the results depend on the processing

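Of the counts given here, those on probes well above background on both arrays, on genes with all probes past 2-fold and on genes with dim probes at their bounds were chosen only after the result was seen. No paired analysis was possible because the labels share only the number 1, so no replicate block can be fitted; arrays of one age are compared within that age by the limma model, which holds age as a term. Leaving out each array in turn was not run, as no residual degree of freedom is left.

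At 24 hpf (3406 probes higher, 2198 lower) the counts were 5188 and 950 under 75th-percentile scaling, 1731 and 482 under normexp, 638 and 76 at 4-fold, 442 and 756 by brightest probe, 374 and 710 with dim probes at bounds, 87 and 57 by genes with all probes past 2-fold, and 2198 and 3406 with the treatment as file names give it. At 96 hpf (1872 higher, 1139 lower) they were 1109 and 290 under normexp, 1226 and 615 with detection on all 4 arrays, 453 and 171 at 4-fold, 699 and 266 by brightest probe, 669 and 203 with dim probes at bounds, 219 and 65 by genes with all probes past 2-fold, and 1139 and 1872 with the treatment as file names give it; probes well above background on both arrays gave 635 lower. The counts of genes with all probes past 2-fold cover only the 7096 genes with 2 or more detected probes. Fewer probes or genes also entered the counts on all 4 arrays, on both arrays, by gene and at bounds. At bounds 8 genes, not 27, were higher at both ages, with bounds and the leaving out of genes dim on both arrays not separated. The 4-fold and file-name counts follow from their construction, and for the normalizations the cause was not tested. The limma copper model called 0 probes under each alternative run, with 538 to 897 probes at an unadjusted p under 0.05. Without a filter, 2635 probes were lower at 96 hpf than at 24 hpf, against 5670, and 7 of 16 exocrine pancreas genes rose, against 11; the cause was not tested.

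The r of the 24 hpf difference with age moved to -0.018 under 75th-percentile scaling; that at 96 hpf stayed between 0.50 and 0.54. Under normexp 3 lists, not 5, lay below at 24 hpf. List calls held in every alternative for 4 of 5 lists above and 2 of 5 below at 24 hpf, and for 11 of 14 above and 6 of 8 below at 96 hpf. Among lists outside random lists at 24 hpf, the median of heat shock turned sign under normexp (-0.023). Under 75th-percentile scaling the unfolded protein response turned to -0.041 and muscle to -0.26. Cell cycle turned to 0.0095 under normexp, 0.40 with the mean of detected probes and 0.002 with the mean of the list. Each stayed above the random lists, except heat shock in 1 alternative. The mean of detected probes moved heat shock to 0.79 and the unfolded protein response to 0.65. Turns of sign in lists inside random lists were not counted, and the cause was not tested. Of 748 values of named genes under the scalings and filters, 262 moved and 486 did not. No difference past 2-fold turned sign, which shows little, since the naming rule required one sign under 3 normalizations for the largest differences. Genes not well above background on an array have only a bound there.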

Other observations

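Other groups of genes also stood apart at 96 hpf. Genes of xenobiotic metabolism had a median of 0.65, with 7 of 20 higher by 2-fold or more in the array labelled copper, among them the cytochrome cyp3a65 (12.8-fold), cyp2ad2 (7.83-fold) and the glucuronosyltransferase ugt1a1 (4.14-fold). Circadian clock genes had a median of 0.45, and the repressor nr1d1 was 6.13-fold higher. Genes of oxidative stress and glutathione had a median of 0.24, with the glutathione transferase gstp1.1 4.18-fold higher, while hmox1b was 1.69-fold and the transporter abcc2 2.62-fold lower. Mitochondrial respiratory chain genes were above 0 in 36 of 37 cases, with a median of 0.18. The xenobiotic, circadian clock and respiratory chain lists also rose with age, with median changes of 1.35, 0.64 and 0.42, above their random lists. The change with age of the oxidative stress and glutathione list (median 0.11) lay inside its random lists. Whether a difference in developmental stage accounts for the differences of these lists at 96 hpf was not tested.

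Some genes stood apart from their list. In the myeloid list (median -0.22) the carboxypeptidase cpa5 was 34.8-fold higher at 96 hpf. In the endothelium list (-0.024) the early vascular gene etsrp was 4.36-fold higher at 96 hpf on its single probe. The glycolysis enzyme gpib, a member of none of the lists, was 36.4-fold lower on its single probe at 96 hpf and differed by 0.29 (log2) at 24 hpf. At 24 hpf the immediate early gene fosab was 2.83-fold lower on its brightest probe, with 5 of 5 probes lower, and the clock gene per1b 2.89-fold, with 2 of 2 lower.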
